A study of Drosophila melanogaster with 6 samples.

How the data were processed

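RNA from ovary lysate of wild-type Oregon-R flies was recovered with anti-Lsd1, anti-Bre1 or IgG, in 2 experiments, and sequenced as 6 libraries. Per the labels, a lysate from about 200 females was divided among the 3 antibodies in each experiment, and libraries were made with a TruSeq RNA kit (version 2 protocol) without selection for polyadenylated RNA. This kit does not mark strand, so reads of overlapping and antisense genes cannot be told apart. The submitters' processing notes name TopHat, Bowtie2 2.0.6.0, SAMtools 0.1.18.0, Cufflinks and build dm6; versions of TopHat and Cufflinks are not given in the sources used here.

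The 2 experiments were quantified differently. For experiment 1 the authors deposited Cufflinks tables of FPKM per transcript with confidence limits, together with a coverage signal that was not used as a measurement, per the file headers. For experiment 2 they deposited gene tables of RPKM, TPM and read counts (total, unique, exon, junction and intron reads), per the file headers; the program that made these tables is not given in the sources used here. The design fixed beforehand assumed FPKM throughout. RPKM was used for experiment 2 in its place, so the experiment and the quantification cannot be told apart, and the block for experiment takes up both. TPM was not used in any test. Experiment 1 tables held repeated sheets. The first sheet of each library was used; second sheets were identical to it, and a further Lsd1 sheet lacked 120 of its 34174 transcripts.

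Transcript FPKM was summed per gene. Of 17480 genes in experiment 1 and 17398 in experiment 2, 17021 were joined by FlyBase identifier and 80 by symbol, 17101 in all; 31 had no estimate in a library and 17070 were used. Of these, 17011 symbols were found in the reference gene table, whose start and end equalled those of the files for 99.3% of 13588 symbols. Symbols that a spreadsheet had turned into dates (5) were restored through their identifiers. Genes were tested if their value was at least 1 in at least 2 of the 6 libraries, which left 6687. Libraries were scaled by the median ratio over 1028 genes with a value of at least 1 in all 6 libraries, and log2(scaled value + 1) was analysed, so fold changes of low genes are understated. RNAs shorter than the fragments have FPKM that rests on the program's effective length; 87 tested genes were under 200 bases, and 69 tested genes were listed at 0 in all libraries of experiment 1.

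Each comparison was fitted with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, with antibody and experiment as terms, on all 6 libraries, which share 1 estimate of the spread, with 2 residual degrees of freedom. The mean-variance trend added 119 prior degrees of freedom, so a gene's spread came mostly from genes of like abundance. Calls had a Benjamini-Hochberg adjusted p under 0.05. The experiment was a block because the labels say that a lysate was divided among the antibodies. In a check of this pairing, the deviations of libraries from their antibody means correlated across genes at 0.47 for IgG with Lsd1, 0.51 for IgG with Bre1 and 0.11 for Lsd1 with Bre1. The different quantification of the experiments can by itself make these deviations correlate. The check therefore cannot show that a lysate was shared. With 2 libraries per antibody, no count of other ways to divide the libraries was made. The comparisons, tests, lists, rule for named genes and most alternatives were fixed before the data were examined.

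For genes with 1 transcript and usable limits, fragments of experiment 1 were recovered from the width of the confidence limits that Cufflinks gives. For other genes they were modelled from FPKM, the effective length and a library constant, both taken from the 1-transcript genes. Several transcripts were listed for 7336 of the joined genes. Among low genes with 1 transcript, 83.6% (IgG), 83.0% (Lsd1) and 83.9% (Bre1) of the recovered values were whole within 0.05 of a fragment. Outside ribosomal RNA the recovered and modelled fragments came to 1442284 for IgG, 1591527 for Lsd1 and 208851 for Bre1, and the exon reads of experiment 2 to 8739562, 1619605 and 7447852. These fragments and the read counts of experiment 2 were used for depth and for edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as alternatives. Other alternatives were a fit without the block, pseudocounts of 0.1 and 5, no filter, a minimum of 5, values as deposited, quantile and upper quartile scaling, no mean-variance trend, genes of at least 300 bases, and leaving out each library. Genes measured in each experiment, counts in both experiments and removal of the trend on exon length (a lowess curve with a span of 0.3 per ratio) were added after seeing the data.

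Genes were named by a fixed rule. For each antibody over IgG, up to 8 genes per direction with the largest fitted change were taken from those past the threshold with the same sign in both experiments. Where fewer passed, the list was filled with the genes of the largest smaller ratio of the 2 experiments among those at 5 or more in at least 2 libraries. To these were added the 8 noncoding RNAs with the largest smaller ratio among those at 1 or more in at least 2 libraries, and the fixed genes Su(var)3-3, CoRest, Bre1, roX1, roX2, Hsromega, 7SK, the 7SL RNAs, RNase MRP RNA and RNase P RNA. For Lsd1 over Bre1, 5 genes per direction were taken, and examples of a list came from its 3 most abundant members and its members past the threshold.

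Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 and beside it an estimated correlation, adjusted over the 24 lists of a comparison. With an estimated correlation camera uses the 2 residual degrees of freedom, so few lists could pass whatever their correlation. Its adjusted p therefore does not show that correlation among members removes a call. The lists were snRNA, snoRNA, scaRNA, long and other noncoding RNA, named functional noncoding RNAs, mitochondrially encoded genes, cytoplasmic and mitochondrial ribosomal proteins, histones, germline, somatic ovary, piRNA pathway, eggshell, muscle sheath, hemocyte, fat body, gut, heat shock, oxidative phosphorylation, proteasome, translation factors, Lsd1 complex, Bre1 and Paf1 complex, and niche signalling. Lists of precursor microRNAs (0 tested members), tRNAs (0), rRNA (1) and pseudogenes (2) could not be tested. Agreement across experiments was described by correlations and by counts of genes with a ratio of at least 2, beside the number that independent lists would share. For comparisons that share an IgG library, 100 simulations of unchanged groups were drawn.

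The scripts were tested on simulated data made for Lsd1 against IgG over 6687 genes, in 5 draws with 50 changed genes per size. limma recovered 4.00% of genes changed by 1 on the log2 scale, 38.8% at 2, 79.2% at 3 and 94.4% at 4, with 3.40 false calls per draw. Its simulated noise gave a gene the same spread in every library. In the data the SD of the Lsd1 ratio over IgG was 0.38 in experiment 1 and 1.06 in experiment 2. The limma rates therefore do not give its power in these data. edgeR recovered 10.8%, 74.0%, 98.8% and 100% at the same sizes, with 5.40 false calls per draw. Its simulated counts varied less than the data, where its common dispersion was 0.426, and only genes with many reads were changed. These rates therefore do not give its power in these data. A list shifted by 1 was called by camera in 5 of 5 draws, and 0 of 100 unshifted lists were called. Noise was drawn independently for each gene, whereas the estimated correlation within the histone list was 0.90. These draws therefore do not give the rate of false list calls here. In the comparison simulated without change, limma called 1 gene over the 5 draws. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest. Genes of 379 identifiers found only in experiment 1, with copies of ribosomal RNA among those of highest FPKM, were left out of the tests.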

Results

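RNA immunoprecipitation followed by sequencing was used to recover the RNA held by chromatin regulators in the ovary of Drosophila melanogaster. One antibody was against Lsd1, the histone demethylase encoded by Su(var)3-3, one was against Bre1, an E3 ubiquitin ligase that acts on histone H2B, and IgG was the background control. Ovaries of about 200 Oregon-R females, at most 12 hours after eclosion, gave a lysate that was divided among the 3 antibodies. This was done in 2 experiments, so each antibody had 2 libraries and the series had 6. The stated aim was to find noncoding RNAs bound by complexes of either protein, with the IgG library of the same experiment as the reference. The p-values given here rest on the spread of antibody differences between these 2 lysates, part of which may be technical. In limma this spread came mostly from genes of like abundance, so a gene's SE does not show how far its 2 ratios lie apart.

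Most reads in experiment 2 came from ribosomal RNA. Its share of exon reads was 57.6% with IgG (95% Clopper-Pearson interval 57.6 to 57.6), 88.7% with Lsd1 (88.7 to 88.7) and 76.3% with Bre1 (76.3 to 76.3); these intervals cover counting error only. This left 8739562 exon reads outside ribosomal RNA with IgG, 1619605 with Lsd1 and 7447852 with Bre1. In experiment 1 the fragments outside ribosomal RNA, recovered or modelled from the deposited values, were 1442284 with IgG, 1591527 with Lsd1 and 208851 with Bre1. The number of genes with a value of at least 1 FPKM or RPKM was 6243, 6695 and 2036 for IgG, Lsd1 and Bre1 in experiment 1, and 6561, 1416 and 5485 in experiment 2. A value of 1 stands for different numbers of reads in different libraries. Introns took 7.98% of the gene reads outside ribosomal RNA with IgG in experiment 2 (95% Clopper-Pearson interval 7.963 to 7.998), against 2.66% with Lsd1 (2.63 to 2.68) and 1.86% with Bre1 (1.85 to 1.87). The genes udd and brat, picked after the data were seen, held 51.7% of the intron reads with Lsd1, or 22876 of 44214. Without them introns took 7.92% with IgG (95% Clopper-Pearson interval 7.90 to 7.93), 1.30% with Lsd1 (1.28 to 1.32) and 1.86% with Bre1 (1.85 to 1.87).

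The antibody libraries differed from IgG in different ways in the 2 experiments. With Lsd1, the log2 ratio over IgG had an SD over the 6687 tested genes of 0.38 in experiment 1 and 1.06 in experiment 2. With Bre1 the SD was 0.98 in experiment 1 and 0.41 in experiment 2. The median ratio of all tested genes after scaling was 0.03 and -0.84 with Lsd1, and -0.40 and -0.22 with Bre1, in experiments 1 and 2. Without scaling these medians were 0.28, -2.02, -1.34 and -0.74, in the same order. Ratios also depended on transcript length. Among 6496 protein-coding genes, the Bre1 ratio of experiment 1 had a median of -1.26 under 1000 bases of exon and 0.34 over 5000 bases, with a Spearman correlation with length of 0.52 across genes. The same correlation was 0.42 with Lsd1 in experiment 1, and in experiment 2 it was -0.00 with Lsd1 and 0.17 with Bre1.

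**Figure D1:**
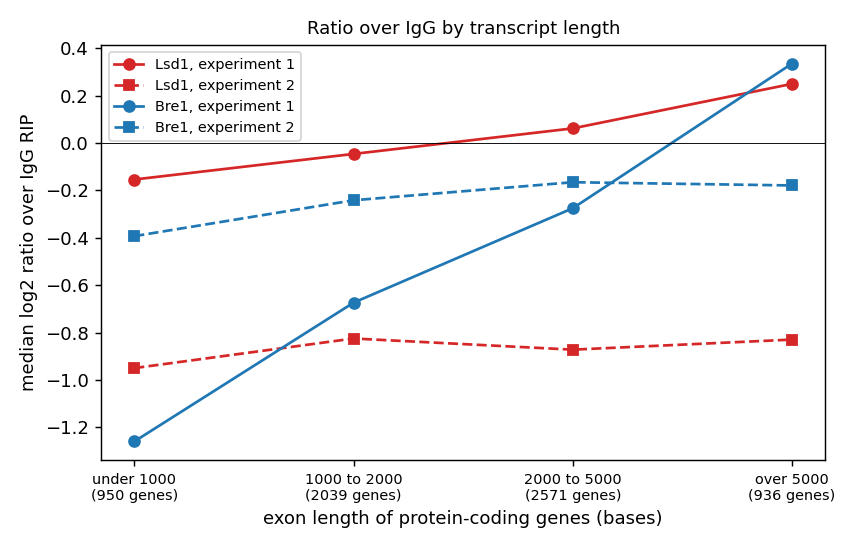
Median log2 ratio over IgG (y axis) of protein-coding genes in 4 classes of exon length in bases (x axis), for each antibody and experiment. The Bre1 ratio of experiment 1 ran from -1.26 in the shortest class to 0.34 in the longest, whereas the Lsd1 ratio of experiment 2 stayed between -0.95 and -0.82.

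The first comparison asked which RNAs were more abundant with anti-Lsd1 than with IgG. A small set of RNAs stood above IgG in both experiments, among them hairpin RNAs, which are long inverted repeats processed into endogenous small interfering RNAs. The hairpin RNA hpRNA:CR33940 (FBgn0062928, chromosome 3L, 19486745 to 19488439, dm6) had log2 ratios of 3.12 in experiment 1 and 4.65 in experiment 2, or 2.36 in the values as deposited, with 2462 fragments against 238 and 2954 reads against 546. Its fitted change was 3.88 ± 0.98 (SE, n = 2 experiments), and its limma adjusted p of 0.115 missed the threshold, while DESeq2 on counts gave an adjusted p of 0.000222 and the alternatives ran from 0.000222 to 1.00. The hairpin RNA hpRNA:CR32205 had ratios of 1.83 and 2.21, and the second was 0.43 in the values as deposited. On unique reads it stood at 2.60-fold in experiment 2, against 4.63-fold on all reads. On the same arm, hpRNA:CR32207 had 2.07 and 1.20, the second turning negative in the values as deposited and standing at 1.48-fold on unique reads, against 2.29-fold on all reads. The mRNA of Arc1, a gene related to retrotransposon Gag proteins (FBgn0033926, chromosome 2R, 14357927 to 14360297), had ratios of 2.57 and 3.04, the second 0.89 in the values as deposited, and a fitted change of 2.80 ± 0.78 (limma adjusted p = 0.283).

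Some small RNAs named by the rule or fixed beforehand had positive ratios with Lsd1, of which none passed in limma, whereas scaRNAs as a list lay at -1.87 in experiment 2 less the median of all tested genes. The U3 snoRNAs, which act in cleavage of the ribosomal RNA precursor, had ratios of 1.18 and 5.57 (U3:9B), 1.05 and 7.23 (U3:54Ab), and 1.05 and 7.05 (U3:54Aa). No read of the U3:54A copies mapped uniquely in experiment 2, so these copies cannot be told apart. The U2 spliceosomal RNAs U2:34ABb and U2:34ABc had 1.05 in experiment 1 and 0.93 and 0.90 in experiment 2, values that turn negative without scaling and rest on reads of which none was unique. In experiment 2 alone, the signal recognition particle RNA 7SLRNA:CR42652 had a ratio of 9.26 and its copy 7SLRNA:CR32864 had 9.21, from 193848 and 193796 reads with Lsd1, against -0.38 for both in experiment 1. None of these reads was unique, so the copies cannot be told apart, and quantile normalization gives 4.71 and 4.48 in place of the experiment 2 ratios. RNase P RNA, also without unique reads in experiment 2, had -0.20 and 5.10, the first turning positive without scaling and under quantile normalization. RNase MRP RNA had 0.37 and 4.60, and 7SK, the RNA that holds the elongation factor P-TEFb inactive, had 0.61 and 3.63, the second being 0 under quantile normalization.

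Lower values with Lsd1 in both experiments were seen for mt:ND1, a mitochondrial subunit of respiratory complex I, with ratios of -2.99 and -3.32 (95 fragments against 776, and 136 reads against 8170). The ribosomal protein mRNAs RpL10 and RpL15 had -1.62 and -4.79, and -1.39 and -5.02. Further values were -1.25 and -1.31 for the mitochondrial small ribosomal RNA mt:srRNA, -1.25 and -2.19 for the mitochondrial ribosomal protein gene mRpS21, and -1.16 and -2.74 for the noncoding RNA CR40469. In experiment 2 mRpS21 had 0 reads with Lsd1 against 162 with IgG, so its second ratio depends on the pseudocount. For Sps2, a selenophosphate synthetase gene, the ratios were -1.81 and -1.21, although the estimated fragments of experiment 1 were nearly equal, 59 against 64. Its second ratio was -2.13 as deposited and -0.12 under quantile normalization. The transcript of Lsd1's own gene, Su(var)3-3, had 0.09 and -1.09, the second -2.29 as deposited and -0.02 under quantile normalization. That of its partner CoRest had -0.01, positive without scaling, and -0.10, positive under quantile and upper quartile scaling. The Bre1 transcript had 1.27 and -0.32, the second turning positive under quantile and upper quartile scaling. The nuclear noncoding RNA Hsromega had 0.08 and -2.57. The dosage compensation RNAs roX1 and roX2 were below the expression filter and were not tested.

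In limma with the experiment as a block, 1 of 6687 genes rose and 1 fell at an adjusted p under 0.05, and 157 genes had an unadjusted p under 0.05, where chance alone gives 334. The gene that rose was mt:ND4L, a mitochondrial gene of complex I that overlaps mt:ND4 (FBgn0013683, mitochondrial genome, 9545 to 9835), with ratios of 2.44 and 6.45, a fitted change of 4.44 ± 0.97 and a limma adjusted p of 0.0394. These rest on 19 fragments against 2 and 602 reads against 10. With Bre1 the same gene had a ratio of 7.19 in experiment 1, from 78 fragments, and 2 reads in experiment 2. The gene that fell was snoRNA:Psi18S-531, which lies within RpL22 (FBgn0083027, chromosome X, 763083 to 763234), with a fitted change of -4.61 ± 0.87 (limma adjusted p = 0.00377) and no unique reads in experiment 2. Its change came from experiment 1, where it had 16 fragments with IgG and 0 with Lsd1, so that the ratio of -9.16 depends on the pseudocount; the ratio of experiment 2 was -0.06 and turns positive under quantile and upper quartile scaling. The call of mt:ND4L was lost without IgG replicate 1 (a fitted change of 3.56), IgG replicate 2 (5.32) or Lsd1 replicate 2 (0.56), and that of Psi18S-531 without IgG replicate 1 (-0.10) or Lsd1 replicate 1 (-2.29). The number of called genes was 0 without IgG replicate 1, 1805 without Lsd1 replicate 1, 9 without Lsd1 replicate 2 and 5 without Bre1 replicate 2; it was 0 without the replicate block, 0 with edgeR on counts and 10 with DESeq2. Among these 10 were mt:ND4L, hpRNA:CR33940, Arc1, the U3 snoRNAs named above and RNase P RNA (DESeq2 adjusted p from 5.68e-05 to 0.0231; over all alternatives from 3.74e-05 to 1.00).

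**Figure D2:**
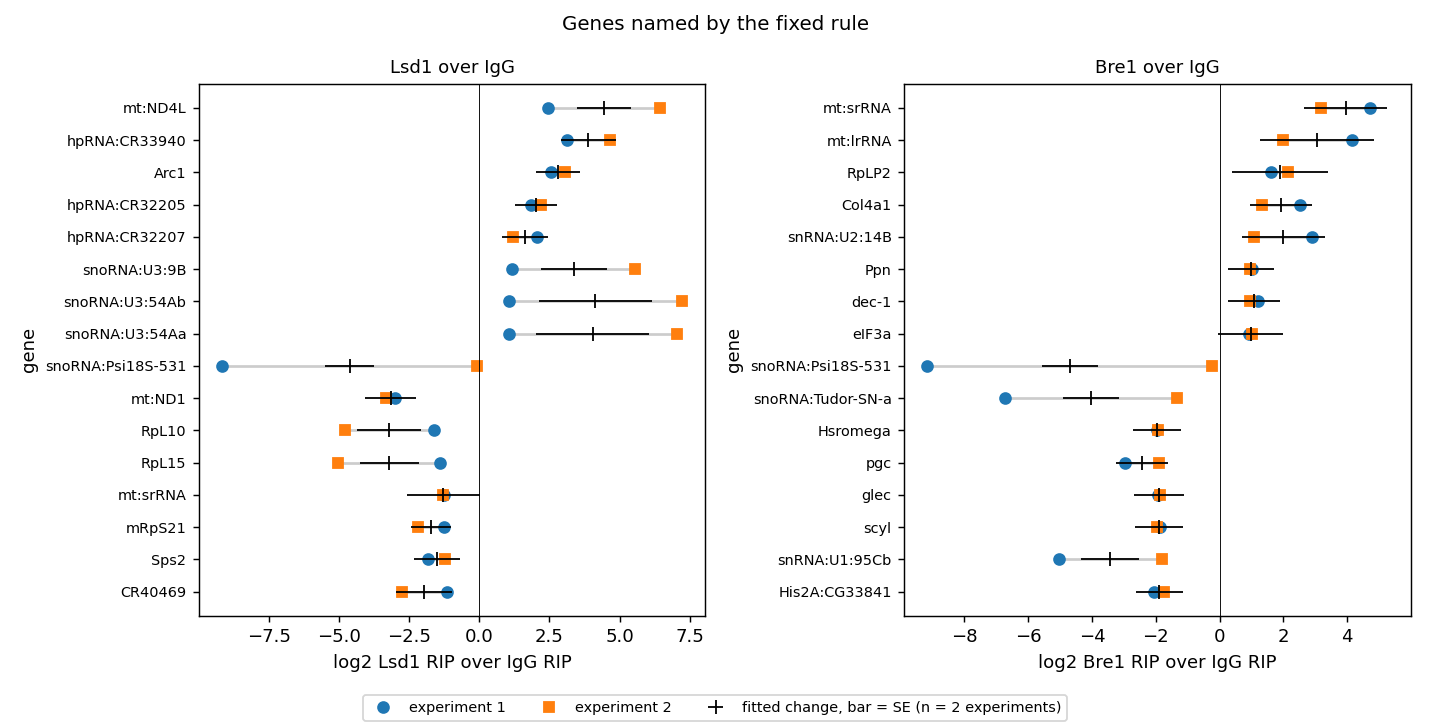
Log2 ratio over IgG (x axis) of the genes named by the fixed rule (y axis), for Lsd1 on the left and Bre1 on the right, with 1 circle for experiment 1, 1 square for experiment 2 and a bar for the SE of the fitted change (n = 2 experiments). hpRNA:CR33940 had ratios of 3.12 and 4.65 with Lsd1 and mt:srRNA had 4.73 and 3.19 with Bre1, whereas snoRNA:Psi18S-531 lay at -9.16 in experiment 1 and near 0 in experiment 2; the experiment 2 ratio of hpRNA:CR32207 and the experiment 1 ratios of RpLP2, Ppn, dec-1 and eIF3a turn negative without scaling.

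Gene lists fixed before the data were examined were compared with all other genes, and their medians are given here less the median of all tested genes. With Lsd1 the spliceosomal and other small nuclear RNAs (24 tested) lay at -0.03 in experiment 1, where many were listed at 0 and the value is 0 under upper quartile scaling, and at 2.30 in experiment 2. Mitochondrially encoded genes (14) lay at -0.67 and 3.17, and snoRNAs (61) at -0.03, which is likewise 0 under upper quartile scaling, and 0.88. By camera with its preset correlation the adjusted p was 7.00e-13 for small nuclear RNAs, 7.00e-13 for mitochondrially encoded genes and 5.46e-12 for snoRNAs, all upward. With an estimated correlation the camera adjusted p was 0.568, 0.568 and 0.285. The estimated correlation of the snoRNAs was -0.0075, below the preset, so correlation among members does not account for their higher adjusted p. In limma adjusted over the list alone, 4 small nuclear RNAs were higher and 1 lower, 3 mitochondrial genes higher and 1 lower, and 3 snoRNAs higher and 1 lower. Germline genes (35) lay at 0.17 and -0.92, with osk, whose mRNA is placed at the oocyte's posterior pole, at 0.45 and -5.13 before the median is taken off. Genes of the piRNA pathway (27) lay at 0.01, which turns negative without scaling, and -0.64. Both lists were downward by camera, with adjusted p = 0.00203 and 0.00266, against an adjusted p of 0.823 for both with an estimated correlation.

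Lists of somatic and housekeeping genes had upward camera tests for Lsd1 that came from experiment 2. The muscle sheath genes (18) lay at -0.27 and 1.29, somatic ovary genes (17) at 0.04 and 0.91, fat body genes (5) at -0.23, which turns positive under quantile normalization, and 2.32, and heat shock genes (18) at 0.18 and 0.74. Their camera adjusted p was 1.84e-06, 0.00308, 0.00768 and 0.0127, against adjusted p = 0.568, 0.568, 0.664 and 0.792 with an estimated correlation. Among the fat body genes, the yolk protein gene Yp2 had ratios of -0.20 and 1.48. The cytoplasmic ribosomal proteins (85) lay at -0.50 and at 1.32, the latter turning negative under quantile normalization, and histones (114) at -0.04 and 0.84, with 5 histone genes above 0 in experiment 2, where many were listed at 0. Both were upward by camera, with adjusted p = 0.00164 and 0.0105, against an adjusted p of 0.823 for both with an estimated correlation. For these the test stood against the signs of the fitted values, with a median of -0.01 and a mean of -0.19 for ribosomal proteins, and -0.08 and -0.23 for histones; the heat shock median was 0.05 and its mean -0.07. Adjusted over the list alone, no member of these 6 lists or of the germline and piRNA lists passed in limma.

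The other lists did not pass the test for Lsd1. Camera adjusted p was 0.0600 for gut, 0.0600 for mitochondrial ribosomal proteins, 0.0607 for hemocyte, 0.149 for long and other noncoding RNAs, 0.152 for the Bre1 and Paf1 complex and 0.181 for the proteasome. It was 0.182 for translation factors, 0.476 for scaRNAs, 0.476 for the Lsd1 complex, 0.495 for named functional noncoding RNAs, 0.588 for oxidative phosphorylation, 0.891 for eggshell and 0.959 for niche signalling. An upward test stood beside a negative fitted median for the noncoding RNAs (-0.24), the proteasome (-0.28), translation factors (-0.37), the Lsd1 complex (-0.14), the named noncoding RNAs (-1.14, mean 0.49) and oxidative phosphorylation (-0.51). The Bre1 and Paf1 complex had an upward test and a median of 0.02 with a mean of -0.16. In limma adjusted over the list alone, 1 scaRNA was higher and 3 were lower, and 1 long or other noncoding RNA was lower. Without Lsd1 replicate 2, 1 of the 11 called lists kept its call, and the small nuclear RNAs and mitochondrially encoded genes turned downward (camera adjusted p = 7.06e-19 and 5.65e-10; over all alternatives from 1.06e-22 and 5.07e-16 to 0.568 for both). Without IgG replicate 2, 4 of the 11 kept their call, and ribosomal proteins and histones turned downward (camera adjusted p = 1.33e-08 and 4.84e-07; over all alternatives from 7.78e-15 and 6.78e-28 to 0.823 for both). Without IgG replicate 1 or Lsd1 replicate 1, 10 of the 11 kept it.

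The second comparison asked which RNAs were more abundant with anti-Bre1 than with IgG. Among the named genes, the mitochondrial ribosomal RNA of the small subunit stood furthest above IgG in both experiments after scaling by the median ratio. Under quantile normalization its experiment 1 ratio was 1.93, below that of Col4a1 (3.07). The small subunit RNA mt:srRNA (FBgn0013688, mitochondrial genome, 14131 to 14916) had log2 ratios of 4.73 and 3.19, from 33905 fragments against 8003 and 5807 reads against 582, with a fitted change of 3.96 ± 1.30 (SE, n = 2 experiments; limma adjusted p = 0.786). On counts DESeq2 gave it an adjusted p of 8.72e-05, and over all alternatives the adjusted p ran from 8.72e-05 to 1.00. The large subunit RNA mt:lrRNA had 4.14 and 1.98. Collagen IV, encoded by Col4a1 and a main component of basement membranes, had 2.52 and 1.34, or 0.64 and 0.71 in the values as deposited. The basement membrane gene Ppn had 1.00 and 0.96. RpLP2, a ribosomal stalk protein, had 1.62 and 2.15, the eggshell gene dec-1 had 1.21 and 0.94, and the initiation factor eIF3a had 0.91 and 1.03; for these and Ppn the experiment 1 ratio turns negative without scaling. The U2 spliceosomal RNAs had 2.91 and 1.09 (U2:14B) and 3.27 and 0.77 (U2:34ABa). In experiment 2 U2:14B had 494 reads with Bre1 against 228 with IgG, but 2 against 14 on unique reads. Its second ratio therefore rests on reads that are not unique. For U2:34ABa 1081 reads with Bre1 and 830 with IgG were unique. The copies U2:34ABb, U2:34ABc and U2:38ABa had 3.13, 3.14 and 3.04 in experiment 1 and 0.50, 0.33 and 0.45 in experiment 2, and CR45601 had 1.15 and 0.45, with signs that turn without scaling in 1 of the experiments. None of the experiment 2 reads of U2:34ABb, U2:34ABc and U2:38ABa was unique.

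Below IgG in both experiments were Hsromega, the stress-induced nuclear noncoding RNA (FBgn0001234, chromosome 3R, 21296127 to 21317836), with ratios of -1.98 and -1.93, and pgc, which represses transcription in the germ cell precursors, with -2.96 and -1.91. The mRNA of glec had -1.93 and -1.87, that of scyl, an inhibitor of growth signalling, had -1.86 and -1.96, and the histone gene His2A:CG33841 had -2.05 and -1.74. The U1 spliceosomal RNA U1:95Cb had -5.03 and -1.82, the first from 1 fragment with IgG and 0 with Bre1. None of the experiment 2 reads of His2A:CG33841 or U1:95Cb was unique. Transcripts of the complexes themselves did not pass the test. Su(var)3-3 had -0.09 and -0.26, signs that turn under quantile normalization, CoRest had 0.90, negative without scaling, and -0.41, and Bre1 had 1.10, negative without scaling, and -0.22, positive under upper quartile scaling. Values for 7SK were 0.94 and 0.31 and for RNase P RNA -0.09 and 0.08, signs that turn without scaling or under quantile normalization. The 7SL RNAs had 1.75 (CR42652) and 1.76 (CR32864) in experiment 1, which turn negative without scaling and under quantile normalization, and -0.79 and -0.77 in experiment 2. RNase MRP RNA had 0.03, negative without scaling, and 1.39.

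By limma no gene rose with Bre1 and 2 fell, with 260 genes at an unadjusted p under 0.05 where chance gives 334. On counts edgeR called 0 genes and DESeq2 called 1, mt:srRNA, as higher. The genes that fell were snoRNA:Psi18S-531, with a fitted change of -4.69 ± 0.87 (limma adjusted p = 0.00242), and snoRNA:Tudor-SN-a, which lies within Tudor-SN (FBgn0263470, chromosome 3L, 259970 to 260280), with one of -4.03 ± 0.87 (limma adjusted p = 0.0310). Psi18S-531 had ratios of -9.16 and -0.23, the second turning positive under quantile normalization, and Tudor-SN-a had -6.73 and -1.32, with 183 fragments with IgG and 0 with Bre1 in experiment 1, so that its first ratio also depends on the pseudocount. The call of Psi18S-531 was lost without IgG replicate 1 (a fitted change of -0.19), Lsd1 replicate 1 (-4.69) or Bre1 replicate 1 (-2.51). That of Tudor-SN-a was lost without the same libraries (-2.86, -4.03 and -1.13) or without IgG replicate 2 (-5.19). The number of called genes was 0 without IgG replicate 1, Lsd1 replicate 1 or Bre1 replicate 1, 4 without IgG replicate 2, 43 without Lsd1 replicate 2, 44 without Bre1 replicate 2 and 0 without the replicate block.

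Lists of short mRNAs stood low with Bre1, chiefly in experiment 1. Less the median of all tested genes, histones (114) lay at -1.65 and 0.22, the latter turning negative under quantile normalization, and cytoplasmic ribosomal proteins (85) at -1.88 and 0.24. Mitochondrial ribosomal proteins (73) lay at -0.96 and -0.12, and oxidative phosphorylation genes (67) at -1.18 and 0.01, the latter turning negative without scaling. RpL41, for example, had ratios of -2.49 and -0.66, and ATPsynC had -2.37 and -0.22, before the median is taken off. By camera these lists were downward with adjusted p = 1.19e-25, 1.52e-05, 3.36e-08 and 1.19e-06, in the order given. With an estimated correlation the camera adjusted p was 0.923 for each. Within the histone list the estimated correlation was 0.90, against the preset 0.01, so its 114 members do not count as separate genes. Median exon lengths were 529 bases for histones, 927 for ribosomal proteins, 783 for mitochondrial ribosomal proteins and 871 for oxidative phosphorylation.

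Upward lists with Bre1 were the mitochondrially encoded genes (14), at 1.81 and 0.10, somatic ovary genes (17), at 0.85 and 0.18, hemocyte genes (4), at 1.03 and 0.58, and snoRNAs (61), at 0.40, where many were listed at 0 and the median ratio itself was 0, and 0.13. Camera adjusted p was 4.70e-10, 0.000872, 0.0379 and 0.0379, and adjusted p = 0.762 for each of them with an estimated correlation. For snoRNAs the fitted median was -0.05 and the mean -0.19, against the upward test. The follicle cell gene tj, a transcription factor of somatic gonad cells, had ratios of 0.80 and 0.23. In limma adjusted over the list alone, 3 mitochondrial genes were higher and 1 lower, 2 oxidative phosphorylation genes were lower, 3 snoRNAs were lower and 4 small nuclear RNAs were lower, as were 1 scaRNA and 1 long or other noncoding RNA. Of the lists that did not pass, camera adjusted p was 0.0707 for scaRNAs, downward, 0.309 for germline genes, downward, and 0.426 for small nuclear RNAs, downward. The remaining lists had a camera adjusted p between 0.0741 (heat shock) and 0.874 (muscle sheath, named and other noncoding RNAs). Among these the test was upward beside a negative fitted median for eggshell, niche signalling, gut, translation factors, the Lsd1 complex, the Bre1 and Paf1 complex and noncoding RNAs, and heat shock had a median of 0.01 and a mean of -0.05. Without Bre1 replicate 1, 1 of the 8 called lists kept its call and the mitochondrially encoded genes turned downward (camera adjusted p = 0.0200; over all alternatives from 4.05e-21 to 0.762). Without any one of IgG replicate 1, IgG replicate 2, Lsd1 replicate 2 and Bre1 replicate 2, 6 of the 8 kept it, and 7 did without Lsd1 replicate 1.

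The third comparison set the antibodies against each other within each lysate. Higher with Lsd1 were hpRNA:CR32205, with log2 ratios of Lsd1 over Bre1 of 2.89 and 2.82, CG13751, with 3.44, from 34 fragments against 0, and 2.65, and the spliceosomal protein gene snf, with 2.42, from 100 fragments against 1, and 2.75. In the values as deposited their experiment 2 ratios were 1.54, 1.16 and 1.12, and their limma adjusted p of 0.102, 0.0682 and 0.441 missed the threshold. Lower with Lsd1 was mt:srRNA, with -5.98 and -4.50, a fitted change of -5.24 ± 1.30 (SE, n = 2 experiments) and a limma adjusted p of 0.0724. On counts the DESeq2 adjusted p was 8.24e-07 for mt:srRNA and 0.00328 for hpRNA:CR32205, and over all alternatives the adjusted p ran from these values to 1.00. Claspin, a checkpoint gene, had -2.43 and -1.39. CR42862 had -1.42 and -2.39, Sas10 had -1.40 and -2.05, and CG33713 had -1.37 and -1.45, with experiment 1 ratios that turn positive without scaling.

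By limma 5 genes were higher with Lsd1 than with Bre1 and none lower, all of them small RNAs, with 81 genes at an unadjusted p under 0.05. The spliceosomal RNAs snRNA:U6:96Ab and snRNA:U6:96Ac rose by 3.66 ± 0.77 and 3.63 ± 0.78 (limma adjusted p = 0.0223 for both), and snoRNA:Psi28S-3436b rose by 3.42 ± 0.78 (limma adjusted p = 0.0380). All of these were listed at 0 throughout experiment 1; in experiment 2 they had 300, 342 and 437 reads with Lsd1 and 0, 2 and 7 with Bre1, and they were named outside the fixed rule after their values were seen. snoRNA:Tudor-SN-a rose by 4.01 ± 0.87 and scaRNA:PsiU2-55 by 3.70 ± 0.86 (limma adjusted p = 0.0223 and 0.0496), with ratios of 7.10 and 0.92, and 7.19 and 0.22; both experiment 2 ratios turn negative without scaling. In experiment 1 they had 265 and 10 fragments with Lsd1 and 0 with Bre1, so those ratios depend on the pseudocount. None of the experiment 2 reads of these 5 RNAs was unique. The number of called genes was 0 without IgG replicate 1 or IgG replicate 2, 39 without Lsd1 replicate 1, 20 without Lsd1 replicate 2, 9 without Bre1 replicate 1 and 8 without Bre1 replicate 2. The count was 0 with edgeR, 8 with DESeq2 and 0 without the replicate block. The U6 copies and Psi28S-3436b also lost their call without Lsd1 replicate 2 (fitted changes of 0.26, 0.14 and 0.28) or Bre1 replicate 2 (1.57, 1.67 and 1.43). Tudor-SN-a and PsiU2-55 lost it without Lsd1 replicate 1 (2.28 and 1.71) or Bre1 replicate 1 (1.11 and 0.47).

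Among lists, medians of the fitted Lsd1 over Bre1 change are given less that of all tested genes, which was -0.10 after scaling and 0.19 without. They were 1.11 for histones, 1.14 for cytoplasmic ribosomal proteins, 1.60 for small nuclear RNAs, 1.16 for fat body, 0.89 for muscle sheath, 0.58 for oxidative phosphorylation, 0.52 for the proteasome and 0.35 for mitochondrial ribosomal proteins. The piRNA pathway lay at -0.20, and snoRNAs at 0.61, or at -0.31 without scaling. All 10 passed camera, with adjusted p from 1.20e-44 for histones to 0.0248 for the piRNA pathway. The estimated correlation within the histone list was 0.90, so its members do not count as separate genes. With an estimated correlation camera called none, with adjusted p = 0.781 for small nuclear RNAs, muscle sheath and snoRNAs and 0.810 for the other 7. In limma adjusted over the list alone, 8 small nuclear RNAs and 8 snoRNAs were higher and 1 snoRNA was lower. Likewise 2 scaRNAs, 2 long or other noncoding RNAs and 1 mitochondrial gene were higher, and 1 mitochondrial gene was lower. The test was upward beside a negative median or mean for scaRNAs, heat shock and mitochondrially encoded genes, which did not pass. Without Lsd1 replicate 2, 3 of the 10 called lists kept their call and small nuclear RNAs turned downward (camera adjusted p = 0.00611; over all alternatives from 3.11e-47 to 0.911). The number that kept it was 7 without Bre1 replicate 1 or Bre1 replicate 2 and 9 without Lsd1 replicate 1.

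The remaining comparisons asked whether the experiments gave the same RNAs. A ratio of at least 2 over IgG in both experiments was found for 8 genes with Lsd1, where independent lists would share 1.19, and for 5 genes with Bre1, where independent lists would share 0.831. The 8 genes include U3:54Aa and U3:54Ab, whose reads cannot be told apart, so these copies do not count as independent genes. The 5 genes with Bre1 include U2:14B, which had 2 unique reads with Bre1 against 14 with IgG in experiment 2. In the other direction, 14 genes were lower by at least 2-fold in both experiments with Lsd1 and 130 with Bre1, against 14.9 and 63.0 for independent lists. Across the 6687 genes, which are not independent replicates, the log2 ratios of the experiments had a Pearson correlation of -0.09 (Spearman -0.15) for Lsd1 and 0.21 (Spearman 0.18) for Bre1. Between antibodies, with no library in common, the correlation was -0.12 for Lsd1 in experiment 1 with Bre1 in experiment 2, and 0.28 for Lsd1 in experiment 2 with Bre1 in experiment 1; these are 4 of 6 relations computed.

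Within an experiment the antibodies share an IgG library. Lsd1 and Bre1 ratios had a correlation of 0.37 in experiment 1 and 0.51 in experiment 2, where unchanged groups simulated against the shared control gave 0.50 in each. The covariance was 0.139 and 0.219, below the simulated 0.481 in both experiments. Genes at least 2-fold above IgG with both antibodies numbered 14 in experiment 1 (independent lists 1.32, simulated 381) and 7 in experiment 2 (independent lists 0.747, simulated 382). The simulation gave every library the residual spread of the fit over the 6 libraries. Its overlaps exceed all genes 2-fold above IgG with Lsd1 in experiment 1 (27) or with Bre1 in experiment 2 (17). It therefore cannot show how much of the overlap the shared IgG explains. With 1 IgG library per experiment the controls could not be divided, so part of the overlap may come from them. Without a shared library, 1 gene was above IgG with Lsd1 in experiment 1 and Bre1 in experiment 2 (0.0686 for independent lists), and 45 with Lsd1 in experiment 2 and Bre1 in experiment 1 (14.4 for independent lists).

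**Figure D3:**
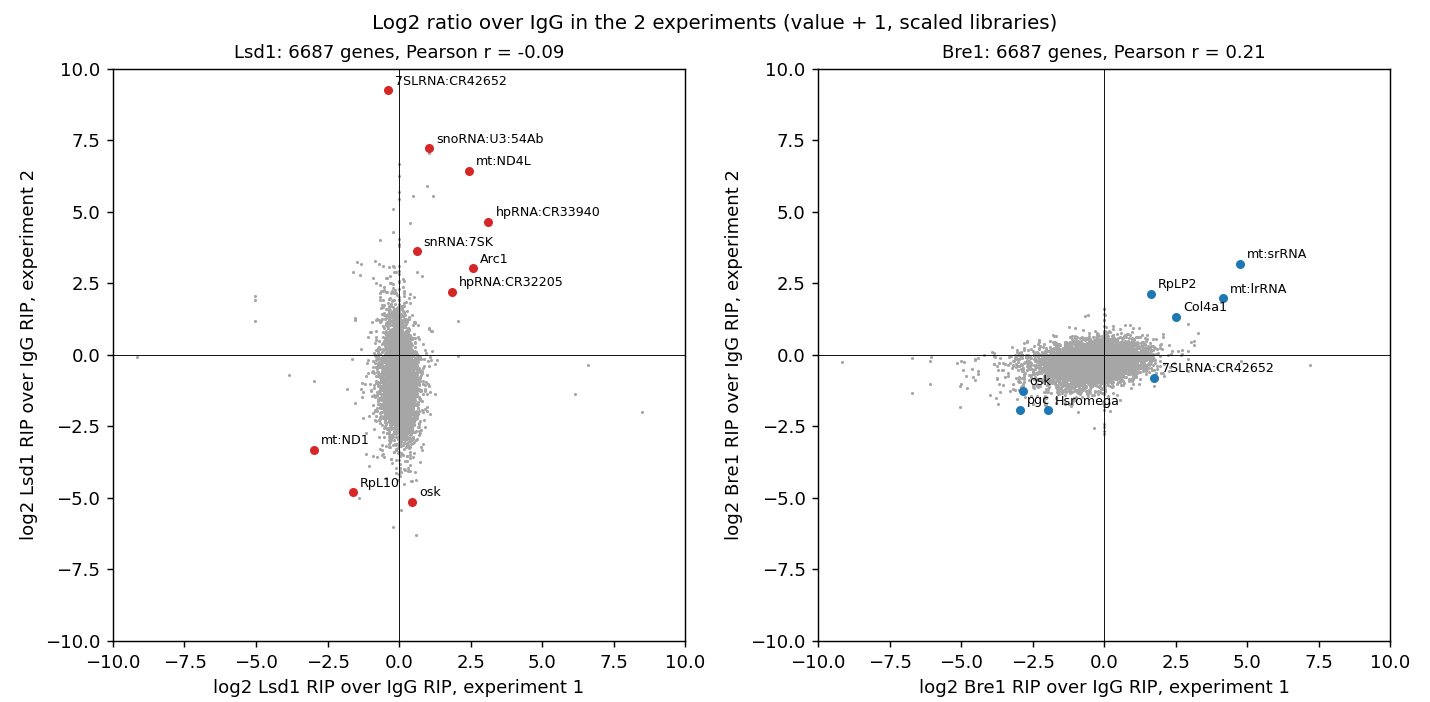
Log2 ratio over IgG in experiment 1 (x axis) and experiment 2 (y axis) of 6687 genes, 1 point per gene, for Lsd1 on the left and Bre1 on the right. The Pearson correlation was -0.09 for Lsd1, where the spread lies along the axis of experiment 2, and 0.21 for Bre1, where it lies along that of experiment 1.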

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

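All tests of the weighed patterns are in the part on other observations; the signals here were looked at only after the data were seen and were not tested.

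Some data lie outside the comparisons and stood above IgG. Genes listed only in experiment 1, with copies of ribosomal RNA among those of highest FPKM, were left out of the tests. Their summed FPKM was 699665 with Bre1, against 483868 with IgG and 391902 with Lsd1, in 1 library each. Of the Bre1 sum, 606312 lay in 10 genes. Among these CR40642 stood at 74242 with Bre1 and at 0 with IgG and Lsd1. The copy 28SrRNA-Psi:CR41609 went the other way, at 32385 with Bre1 against 98295 with IgG. How reads were divided among such genes was not examined. Reads in introns were counted in experiment 2 but not tested. In udd, the RPM of intron reads, over reads outside ribosomal RNA, came to 10236 with Lsd1, against 86.7 with IgG, from 16579 and 758 reads. In brat they came to 3888 against 749, from 6297 and 6543 reads. The brat signal therefore comes from near equal read numbers in libraries of different depth. Whether unlisted RNAs lie within these introns was not analysed here.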

How the results depend on the processing

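Restricting the genes to those measured in each experiment, removing the length trend and using counts for the agreement were tests chosen only after the results were seen. Counts of called genes are given as Lsd1 against IgG (2), Bre1 against IgG (2) and Lsd1 against Bre1 (5). They were 0, 0 and 0 without the replicate block, with a pseudocount of 0.1, with no filter, with values as deposited, with quantile normalization, with upper quartile scaling and with edgeR on counts, and 0, 0 and 1 with no mean-variance trend. They were 15, 1 and 15 with a pseudocount of 5, 6, 4 and 9 when measured in each experiment, and 10, 1 and 8 with DESeq2 on counts. With a minimum FPKM of 5 the Bre1 count was 5, and with genes of at least 300 bases the Lsd1 counts were 1 and 1. Leaving out 1 library gave 0 to 1805, 0 to 44 and 0 to 39 genes, and 4 to 15, 6 to 12 and 7 to 13 called lists, where the lone sample of an antibody was assumed to vary like the others. No list was called with an estimated correlation (0, 0 and 0), a form of the test that few lists could pass with 2 residual degrees of freedom. The cause was not tested, except that fewer genes were tested at the higher minimum and length.

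Genes above IgG by 2-fold in both experiments with Bre1 (5) numbered 8 with a pseudocount of 0.1, 2 as deposited, 21 with quantile normalization and 10 with upper quartile scaling; with Lsd1 (8) they numbered 4 among genes of at least 300 bases. Overlaps of Lsd1 in experiment 1 with Bre1 in experiment 2 (1), of Lsd1 in experiment 2 with Bre1 in experiment 1 (45), and within experiments 1 (14) and 2 (7) were 2, 76, 31 and 12 with a pseudocount of 0.1. With a pseudocount of 5 the first 3 were 0, 22 and 9. As deposited the overlaps were 0, 3, 9 and 0. The first, the second and the last were 2, 170 and 28 with quantile normalization and 2, 71 and 27 with upper quartile scaling. Among genes of at least 300 bases the overlaps were 0 for the first and 6 within experiment 1.

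Called lists that reversed did so downward. By camera, without Lsd1 replicate 2 these were small nuclear RNAs (adjusted p = 7.06e-19 against IgG and 0.00611 against Bre1) and, for Lsd1 against IgG, mitochondrially encoded genes (adjusted p = 5.65e-10). Without IgG replicate 2 they were ribosomal proteins and histones for Lsd1 against IgG (camera adjusted p = 1.33e-08 and 4.84e-07), and without Bre1 replicate 1 mitochondrially encoded genes for Bre1 (camera adjusted p = 0.0200). With each library left out in turn, the camera adjusted p for Lsd1 against IgG ran from 8.88e-22 to 0.0146 for small nuclear RNAs, from 5.07e-16 to 4.13e-06 for mitochondrially encoded genes, from 7.78e-15 to 0.507 for ribosomal proteins and from 3.58e-12 to 0.546 for histones. It ran from 4.05e-21 to 0.0200 for mitochondrially encoded genes with Bre1 against IgG and from 3.11e-47 to 0.911 for small nuclear RNAs with Lsd1 against Bre1. snoRNAs in Lsd1 against Bre1 reversed with no filter, as deposited and with the length trend removed (camera adjusted p = 0.00414, 5.11e-05 and 4.01e-15; over all alternatives from 4.01e-15 to 0.781). The cause was not tested. Of the values of called lists under the alternatives, 403 kept their side of the threshold and direction, 104 lost the call and 9 reversed; of those of named genes, 1070 kept their side, 112 lost a call, 39 gained one and 50 changed sign with no call on either side. The 208851 fragments of Bre1 replicate 1 limit what can be seen of weakly expressed RNAs in experiment 1.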

Other observations

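The tests of exchanged labels, of quantification programs, of shared copies and of a yield common to any antibody, and the choice of the groups in the next paragraph with the removal of the length trend, were made only after the results were seen.

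Groups of related RNAs showed values beyond the named genes. The 6 tested genes of basement membrane components (Col4a1, LanA, LanB1, LanB2, Ppn and trol) were above IgG with Bre1 in both experiments, 6 of 6 each time, with median log2 ratios of 0.86, or -0.58 without scaling, and 0.99. Less the median of all genes these were 1.26 and 1.21. The genes are long, with a median of 7913 bases of exon, and with the trend on exon length removed the medians were 0.46, with 5 of 6 above 0, and 1.14, with 6 of 6. With Lsd1 the medians were 0.36 and 0.33, the second -1.58 without scaling. Less the median of all genes they were 0.33 and 1.17, and with the trend removed 0.09, with 4 of 6 above 0, and 0.99, with 6 of 6; the difference between the antibodies was not tested for this group. The 3 hairpin RNAs had medians of 2.07 and 2.21 with Lsd1, by which they had been named, and -0.22, positive under quantile normalization, and -0.59 with Bre1. With Bre1, hpRNA:CR33940 had 1.84 in experiment 1, from deposited values of 25.2 against 26.5 with IgG, and -0.50 in experiment 2. Both hpRNA:CR32205 and hpRNA:CR32207 were below 0 with Bre1 in both experiments. Beside 10000 lists of like abundance, the medians of the U3 snoRNA copies lay at the 100 and 60.5 percentiles with Lsd1 and at 53.3 and 79.3 with Bre1 in experiments 1 and 2. Those of the U2 copies lay at 100 and 18.4 with Lsd1 and at 100 and 99.7 with Bre1, and high percentiles in part restate how these copies were named. A low percentile does not make a ratio ordinary, since it compares only RNAs of like abundance. With Lsd1 in experiment 2 the U3 copies ranked within the top 0.15% of all tested genes. The U2 copies ranked within the top 5.13%, except U2:38ABa at 21.7%. Copies of the spliceosomal U4 and U5 RNAs (7) were listed at 0 in experiment 1 and had a median of 2.59 with Lsd1 in experiment 2, or 0.27 without scaling, with 6 of 7 at least 2-fold above IgG, and copies of U1 (5) had 1.20 with Lsd1, or -1.18 without scaling, and -1.09 with Bre1 in experiment 2. In experiment 1 the U1 copies had a median of -5.02 with either antibody, from 0 or 1 fragment per copy with IgG and 0 with the antibodies.

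The Lsd1 ratios of the experiments had a weak negative correlation across genes of -0.09 (bootstrap SE 0.0179), although more genes than independent lists would share stood 2-fold above IgG in both. Genes are not independent replicates, so the bootstrap SE and bounds in this paragraph do not measure the spread between experiments. Shallow reading of Lsd1 replicate 2 as the source of its spread was argued against, since thinning IgG and Bre1 of experiment 2 to its depth gave an SD of 0.44, which is 41.1% of the 1.06 seen with Lsd1. An exchange of Lsd1 and Bre1 labels in 1 experiment stays open: the correlation of Lsd1 in experiment 1 with Bre1 in experiment 2 less that with Lsd1 was -0.0253 (95% bootstrap bounds -0.0735 and 0.0265), while the like difference for Bre1 was 0.0683 (0.0331 to 0.103). Ratios from counts in both experiments gave -0.0756, but the counts of experiment 1 come from the same program as its FPKM, so the quantification programs cannot be told apart from the experiments. Differences in the RNA bound between lysates stay open as untested.

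Lists of short mRNAs were lower with Bre1 than with IgG. Thinning Lsd1 replicate 1 to the depth of Bre1 replicate 1 moved the median of the 339 members by -0.0593, against -1.81 seen with Bre1. Thinning at random keeps the expected share of each gene, so a large move was hardly possible. The values show only that fewer reads alone do not give such a shift. Low RNA input or loss of RNA before sequencing in Bre1 replicate 1 was not tested and stays open. After the trend on exon length was removed, mitochondrial ribosomal proteins went from -0.83 to -0.14 and lost their call (camera adjusted p = 0.0959, over all alternatives from 2.30e-11 to 0.923). The trend as their cause would give this. However, the curve was fitted to all protein-coding genes, members of these lists included, so its removal takes off part of their own shift. The trend as their cause therefore stays open. Cytoplasmic ribosomal proteins went from -1.06 to -0.38, oxidative phosphorylation from -0.96 to -0.28 and histones from -1.19 to -0.17, keeping their call (camera adjusted p = 0.00535, 0.0133 and 0.00180; over all alternatives from 4.05e-27, 7.96e-16 and 7.35e-41 to 0.923 for each), but in experiments 1 and 2 these medians lay on opposite sides of 0 after removal, at -1.16 and 0.35, -0.59 and 0.09, and -0.58 and 0.39, against -2.28 and 0.01, -1.58 and -0.22, and -2.05 and 0.00 before it. The trend as their whole cause cannot be told apart from a further difference in experiment 1, and the antibody itself stays open as untested.

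The 8 noncoding RNAs named for Lsd1 were higher than IgG in both experiments, 3 of them in experiment 2 with a sign that turns without scaling. In experiment 2, reads shared between near-identical copies were argued against for hpRNA:CR33940 and U3:9B, whose reads were nearly all unique. Their ratios on unique reads were 25.1 and 47.4. Shared reads stay open for hpRNA:CR32205 and hpRNA:CR32207, whose ratios went from 4.63 to 2.60 and from 2.29 to 1.48 on unique reads, and for the 4 with no unique reads, so 3 of the 8 kept a ratio of at least 2. Experiment 1 has no count of unique reads, so sharing was not tested there. A yield common to any antibody stays open, since the median of the 8 was 0.71 with Bre1 against 2.70 with Lsd1, and that of the 3 hairpin RNAs was -0.40 with Bre1 (-0.84 to 0.67) against 2.02 with Lsd1, the lowest of which was 1.63. Binding to Lsd1 stays open as untested.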
